A study of Rattus norvegicus with 33 samples.

How the data were processed

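The study sequenced the DNA of cecal contents, the microbial community of the pouch at the start of the large intestine, from 33 rats aged 14 to 15 weeks. The rats were spontaneously hypertensive rats (SHR), an inbred strain that develops high blood pressure, and Wistar Kyoto rats (WKY), the strain they were compared with. The 4 groups held 10 SHR females, 7 SHR males, 9 WKY females and 7 WKY males, as the labels state strain and sex for every sample. Each library came from its own rat, so p-values measure the spread between rats. Every test treats rats of a group as independent, and where rats shared a cage or litter, which the labels do not give, p-values would be too small. The labels named no cage, litter or sequencing batch, and rats of each strain carried their own run of numbers. Processing order and strain could therefore not be told apart.

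DNA was extracted with a bead-based PowerSoil kit and made into Nextera libraries for shotgun sequencing, per the labels' protocols. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 2.6, Trimmomatic 0.36 and DESeq2 (without a version) were used, and the host genome was a rat build. The tool and the database that gave reads their taxa and their functions are not given in the sources used here. A read is named after a reference genome, so related species can share reads, and their calls are not independent. Names of marine bacteria, archaea and eukaryotes are as the deposited tables give them, were not checked against the reads, and may belong to other organisms.

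The authors deposited tables in percent of reads for 5543 bacterial species, 1455 bacterial genera, 37 phyla, 267 archaeal species, 78 viral species and 100 eukaryotic species. The deposited normalized tables hold a signal that is never negative, the read count of each of 8584 taxa or of each of 1057 functional subsystems divided by a size factor of the sample. The authors also deposited the log2 fold changes of their own models, with the p-value and adjusted p-value of each taxon or function past their threshold. Those tables carry further deposited columns, the mean normalized count and the standard error, which are neither percent nor signal. The table of their sequential model of functions was not used here. No column of values belonged to a sample without a group.

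Low values of the deposited tables were whole multiples of what 1 read was worth. Dividing by that step gave whole reads for 100% of the values of each table, with a tolerance of 0.01 read, and for species present in the percent and the normalized table the reads were equal in 100% of values. The total of assigned reads per library ran from 163140 to 886827. Bacteria took 95.1% to 97.9% of them, 77.0% to 87.8% were named to a bacterial species and 84.7% to 93.6% to a bacterial genus. Reads without molecular identifiers are not independent molecules, so depth limits precision from counting alone.

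The design written before the data were examined foresaw edgeR's quasi-likelihood test on raw counts. The tables held percent and normalized values instead, so the main test became limma on log2(normalized value + 1), with a trend in the variance and robust estimation, and the count tests ran on the recovered reads as alternatives. A fold change on this scale understates the change of low taxa. Taxa were kept where at least 7 samples reached a normalized value of 10, which left 4641 of 5999 bacterial species, 1418 of 1455 genera, 125 of 267 archaeal, 7 of 78 viral and 89 of 100 eukaryotic species. All 1057 functions were tested, of which 1024 had at least 1 read. A single fit over all 33 samples with 4 group means gave SHR minus WKY in females and in males, female minus male in SHR and in WKY, and the difference of the strain effects between the sexes (strain by sex). Every test of these comparisons was 2-sided, and a call means a Benjamini-Hochberg adjusted p under 0.05 over all features of the table. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

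On the recovered reads, edgeR with TMM called 172 species between the strains in females, 59 in males, 0 between the sexes of SHR and 79 between the sexes of WKY, and DESeq2 called 244, 174, 0 and 175. The limma counts were 108, 25, 0 and 33.

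The Shannon index (natural log) and the richness (species with at least 1 read) were computed after thinning every library to 131547 bacterial species reads. The Firmicutes to Bacteroidetes ratio was taken as log2 of the phylum shares. Group means were compared by 2-sided exact permutation tests over every split of the rats, 92378 for females of both strains, 3432 for males, 19448 for the sexes of SHR and 11440 for those of WKY. Community composition was compared by exact PERMANOVA on Bray-Curtis distances of species shares. PERMANOVA can also respond to unequal spread within groups, which was not tested. Adjusted p-values of these measures cover the 4 comparisons of each measure. Differences between the sexes in the strain effect were tested with 100000 permutations.

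Lists of genera with a known trait or lineage (21 lists) and of functions (19 lists, of which 18 had members in the table) were fixed before the files were seen. For a genus list the log2 odds of its summed share of bacterial reads (0.5 read added) were compared by exact permutation, and for a function list the mean log2 normalized value of its members. P-values were adjusted over the lists of each kind, and separate counts give the members called when p-values were adjusted over the list alone.

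Taxa and functions named in the text follow a rule fixed at the same time. It takes every phylum with a mean share of at least 0.1%, the 5 genera and 5 species of highest mean share, and for each strain comparison the 6 largest rises and 6 largest falls among called species and among called genera with at least 0.01% in the higher group. For the other comparisons it takes the 5 of lowest p among called species and genera. It adds up to 4 genera per list, the 3 archaea, viruses and eukaryotes of highest mean and the 3 of lowest p among those called. For functions it takes the 5 largest rises and 5 largest falls among called functions with a mean of at least 10, and the 3 of lowest p in the other comparisons. Taxa with an unresolved name could be passed over.

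Alternatives fixed in advance were edgeR with DESeq2's size factors or with library size alone, DESeq2 on taxa, limma on centred log-ratios, no filter or a filter at 100, a fit of only the groups compared, thinned libraries, other pseudocounts for functions, other distances, indices and minimum reads, and leaving out each rat in turn. Alternatives chosen after seeing the data were edgeR with TMM on recovered reads, limma on percent of reads, pseudocounts of 0.5 and 10 for taxa, log2 depth as a term, and fits without the 3 shallowest libraries (SHR female 9, SHR female 10, SHR male 4), without WKY male 5 and 6, or without WKY male 2 and 3. DESeq2 on functions, function lists with libraries scaled to equal totals and phyla on the size-factor scale were also added then.

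The choice of scale moved the strain comparisons of taxa more than those of functions. The median log2 difference of all functions in females was -0.037 on the size-factor scale and -0.031 with equal totals. Function lists kept their sign with equal totals, but nitrate and nitrite passed in males only there (exact permutation, adjusted p 0.0420 against 0.0524). The mean log2 size factor per read was 0.189 in SHR females, 0.192 in SHR males, -0.192 in WKY females and -0.215 in WKY males. On the size-factor scale the median log2 fold change of all species was -0.066 in females and -0.019 in males, and on the percent scale it was 0.290 and 0.362. Values of single taxa and functions are given on the size-factor scale, and shares of phyla and lists on the percent scale, where they are to be read against that shift.

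The limma step was tested on simulated data made from the means and depths of the real samples, with 200 features changed. Of species changed 2-fold it recovered 53.7% between the strains in females, 38.8% in males, 46.3% between the sexes of SHR, 55.2% between those of WKY and 22.4% for strain by sex, and of species changed 4-fold 100%, 94.0%, 95.5%, 94.0% and 80.6%. Of genera changed 2-fold it recovered 86.6%, 79.1%, 91.0% and 89.6% in these comparisons other than strain by sex, and of functions 61.2%, 62.7%, 59.7% and 46.3%. With nothing changed it called 0 or 1 features in each comparison. The simulation drew taxa independently of each other and gave all groups the same spread per feature. Spread differed between the real groups, so these recoveries and null counts hold for equal spread only. Rats of a group were compared for duplicates by chi-square over species reads, and every pair differed by more than sampling noise, with a chi-square per degree of freedom from 3.79 to 125.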

Results

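Cecal bacteria of SHR and WKY rats were compared in 33 animals, 10 SHR females, 7 SHR males, 9 WKY females and 7 WKY males. The most abundant genera and species were common residents of the rodent gut. The median library held 365717 assigned reads in SHR females, 547938 in SHR males, 706634 in WKY females and 688051 in WKY males, so SHR libraries were the shallower ones. Archaea took 0.461 ± 0.0570% of reads (mean ± SD) in SHR females, 0.467 ± 0.0414% in SHR males, 0.382 ± 0.0655% in WKY females and 0.358 ± 0.0608% in WKY males. Eukaryotes took 0.740%, 0.751%, 0.593% and 0.562% in the same order. Viruses took 0.0514 ± 0.0140%, 0.140 ± 0.176%, 0.0555 ± 0.0192% and 0.0628 ± 0.0275%, with SHR male 4 at 0.533%.

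Between the females of the strains, 4 named species of the Bacteroidales, an order with many polysaccharide degraders, were more abundant in SHR, while the order as a list of genera did not pass. Parabacteroides distasonis took 2.07 ± 1.33% of bacterial reads in SHR females (n = 10) against 0.372 ± 0.172% in WKY females (n = 9), with values above the WKY median in 10 of 10 SHR females. Its log2 fold change on the size-factor scale was 1.90 ± 0.46 (limma, adjusted p 0.0264). Bacteroides intestinalis took 0.505 ± 0.212% against 0.114 ± 0.0611% (log2 fold change 1.83 ± 0.32, limma adjusted p 0.00118, higher in 10 of 10). Bacteroides ovatus (1.58 ± 0.44, limma adjusted p 0.0454, higher in 8 of 10, called in 28 of 49 settings) and Bacteroides thetaiotaomicron (1.07 ± 0.30, limma adjusted p 0.0440, higher in 10 of 10, called in 35 of 49 settings) rose as well. The largest rise was that of Clostridiales bacterium Choco116, whose normalized reads averaged 140 ± 150 against 5.74 ± 4.68 (log2 fold change 4.01 ± 0.64, limma adjusted p 0.000959, higher in 10 of 10). Reads named after the marine bacterium Changchengzhania lutea rose by 2.07 ± 0.38 (limma adjusted p 0.00246, higher in 10 of 10).

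Several Clostridium species known for toxins were scarcer in SHR females, while the list of clostridial genera with toxin-forming members did not pass. Clostridium perfringens, a cause of enteritis in many animals, took 0.152 ± 0.0897% against 0.333 ± 0.109% of bacterial reads (log2 fold change -1.65 ± 0.32, limma adjusted p 0.00276, lower in 10 of 10 SHR females than the WKY median). Clostridium septicum fell by 2.02 ± 0.36 (limma adjusted p 0.00129, lower in 10 of 10), Clostridium chauvoei by 1.92 ± 0.36 (adjusted p 0.00268, lower in 10 of 10) and Clostridium baratii by 1.61 ± 0.34 (adjusted p 0.00781, lower in 9 of 10). Limosilactobacillus reuteri, a lactic acid bacterium of the rodent gut, took 1.39 ± 1.37% against 2.81 ± 1.71% (log2 fold change -1.73 ± 0.48, limma adjusted p 0.0449, lower in 8 of 10). Reads named after Vibrio fluvialis, a bacterium of estuaries, fell by 1.52 ± 0.33 (limma adjusted p 0.00781, lower in 10 of 10).

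Of the 5 most abundant species only Limosilactobacillus reuteri passed in females, and it did so in 21 of 49 alternative settings. Lactobacillus johnsonii averaged 2.41% against 7.03% (log2 fold change -2.29 ± 0.68, limma adjusted p 0.0728). Akkermansia muciniphila, which lives on mucin, averaged 0.511% against 6.11% (-3.25 ± 1.16, limma adjusted p 0.136), with 10 of 10 SHR females below the WKY median. Romboutsia ilealis had a log2 fold change of -0.99 (limma adjusted p 0.239), and Muribaculum intestinale took 2.70 ± 0.682% against 2.21 ± 0.795% (limma adjusted p 0.954). The 5 most abundant genera did not pass either, with Bacteroides at 9.74 ± 4.16% against 9.29 ± 5.32% (limma adjusted p 0.793), Muribaculum at 8.39 ± 2.78% against 8.70 ± 4.77% (0.718), Lactobacillus at 3.56 ± 4.04% against 8.96 ± 7.07% (0.109), Romboutsia (0.276) and Akkermansia (0.159).

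In all, limma called 108 of 4641 species between the strains in females, 29 higher and 79 lower in SHR, and 785 had an unadjusted p under 0.05. On percent of reads the split turned to 329 higher and 18 lower among 347 called species, so the direction of the bulk of species depended on the scale, and 46 of the 108 were called on both. Leaving out WKY female 2 left 45 called species and leaving out SHR female 9 gave 148. Counts also moved more than 1.5-fold without SHR female 1 (60), SHR female 2 (62), SHR female 3 (57), SHR female 4 (63), SHR female 7 (69), SHR female 8 (68), WKY female 5 (58), WKY female 7 (70) or WKY female 8 (62).

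Of 1418 genera 13 were called between the strains in females, 6 higher and 7 lower in SHR, with 233 at an unadjusted p under 0.05 (154 were called on percent of reads, 150 of them higher). Gordonibacter (log2 fold change -1.0 ± 0.23, limma adjusted p 0.0181), Arabia (-0.96 ± 0.21, adjusted p 0.0135) and Denitrobacterium (-0.87 ± 0.18, adjusted p 0.00637), gut actinobacteria of the Eggerthellaceae, were each lower in 10 of 10 SHR females than the WKY median. Vibrio (-0.52 ± 0.10, limma adjusted p 0.00530, lower in 10 of 10) and Epilithonimonas (-0.72, limma adjusted p 0.0181, lower in 9 of 10) fell. Changchengzhania (2.07, limma adjusted p 0.00530) and the acid-loving sulfur oxidizer Acidithiobacillus (0.71 ± 0.16, limma adjusted p 0.0115) rose in 10 of 10. Without SHR female 9 the count was 27, and without WKY male 6 it was 22.

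Verrucomicrobia, the phylum of Akkermansia, took 0.603 ± 0.455% of bacterial reads in SHR females against 6.17 ± 7.82% in WKY females (log2 odds -2.53, exact permutation p 0.0129, adjusted p 0.0279). On the size-factor scale it stood at -2.83 (exact permutation, adjusted p 0.0656). Chloroflexi took 0.194 ± 0.0307% against 0.127 ± 0.0370% (0.64, exact p 0.000595, adjusted p 0.00573; 0.25 on the size-factor scale) and Deinococcus-Thermus 0.165 ± 0.0310% against 0.11 ± 0.0321% (0.62, exact p 0.00176, adjusted p 0.00573; 0.22 on the size-factor scale). Planctomycetes took 0.177% against 0.132% (0.44, exact p 0.00105, adjusted p 0.00573; 0.051 on the size-factor scale). Proteobacteria took 11.4 ± 1.24% against 9.34 ± 1.33% (0.33, exact p 0.00160, adjusted p 0.00573), which turned to -0.093 on the size-factor scale. Cyanobacteria took 0.626 ± 0.105% against 0.478 ± 0.0806% (0.39, exact p 0.00313, adjusted p 0.00813), against -0.0021 on the size-factor scale. No phylum passed on that scale (0 by exact permutation, 5 at an unadjusted p under 0.05). On the percent scale the main phyla did not pass, with Firmicutes at 42.9 ± 9.63% against 44.3 ± 13.7% (exact permutation, adjusted p 0.794), Bacteroidetes at 35.5 ± 10.6% against 31.7 ± 14.9% (adjusted p 0.491) and Actinobacteria at 6.25% against 5.80% (adjusted p 0.36). On the size-factor scale Firmicutes stood at -0.41 (exact permutation p 0.0373, adjusted p 0.0970), and Actinobacteria at -0.25 and Bacteroidetes at -0.15, opposite in sign to their shares. Spirochaetes (adjusted p 0.0563), Fusobacteria, Tenericutes and Thermotogae did not pass.

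By Shannon index and thinned richness the reads of SHR females were more diverse. Their Shannon index averaged 6.05 ± 0.218 against 5.39 ± 0.392, a difference of 0.661 (exact permutation p 0.000141, adjusted p 0.000563), and their thinned libraries held 5147.9 ± 60.9 against 4943 ± 113 species, a difference of 205 (exact permutation p 0.000152, adjusted p 0.000606). Without thinning the richness difference was -76.7 (exact permutation, adjusted p 0.532), and the WKY libraries were the deeper ones. Most of the 5543 bacterial species names had a read in the thinned libraries, so richness counts names and not residents. Names were not checked against the reads, and a larger share of misassigned reads in SHR would raise both measures too, which was not tested. Strain accounted for 0.198 of the Bray-Curtis variation among females (exact permutation p 0.00840, adjusted p 0.0336), which did not pass on genera (R2 0.178, adjusted p 0.0876). Unequal spread can also move this test, and the Shannon SD was larger in WKY females. The log2 ratio of Firmicutes to Bacteroidetes averaged 0.32 ± 0.81 against 0.58 ± 1.11 (difference -0.26, exact permutation p 0.550).

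**Figure D1:**
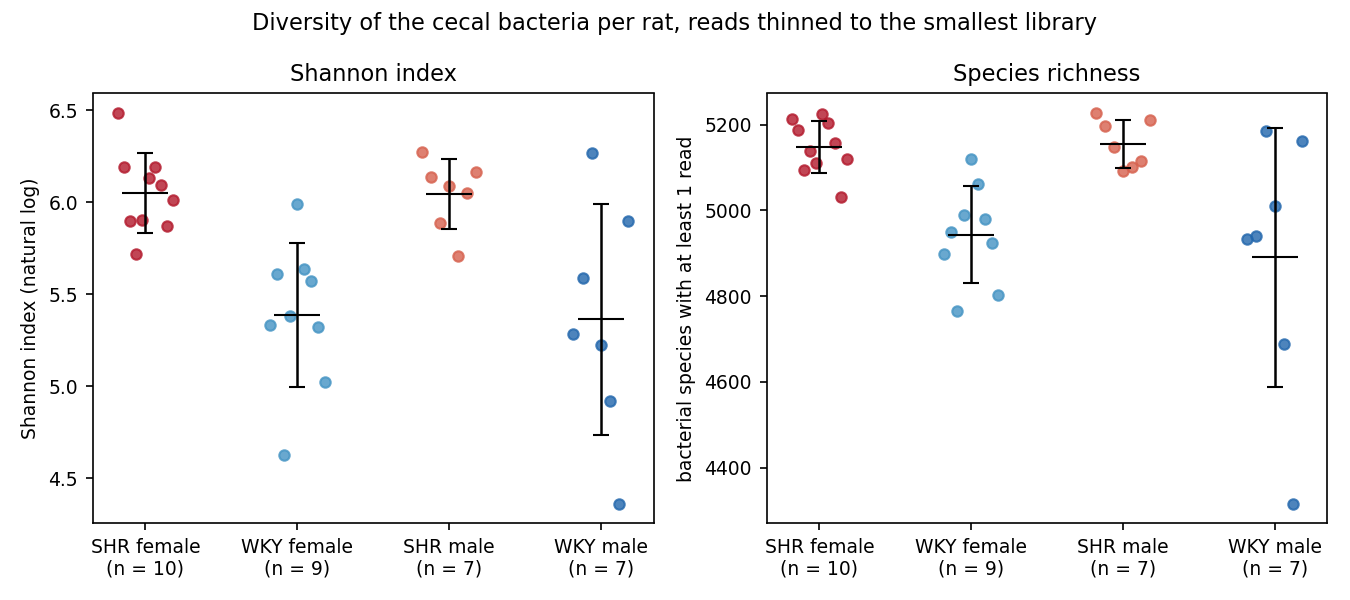
Shannon index and species richness of each rat after thinning to equal reads, with group mean and SD. In males the mean Shannon index of SHR was higher by 0.681 and in females by 0.661.

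Butyrate producers such as Roseburia and Faecalibacterium, which ferment fibre, took 6.07 ± 1.10% of reads in SHR females against 4.11 ± 0.960% in WKY females (log2 odds 0.60, exact permutation p 0.000920, adjusted p over lists 0.00644), with a mean centred log-ratio difference of 0.167. Sulfate reducers such as Desulfovibrio took 0.390 ± 0.0460% against 0.286 ± 0.0516% (0.46, exact p 0.000336, adjusted p 0.00644; centred log-ratio difference 0.181). Negativicutes such as Selenomonas took 0.383 ± 0.0609% against 0.275 ± 0.0582% (0.49, exact p 0.000628, adjusted p 0.00644; centred log-ratio difference 0.153). Mucus layer residents, here Akkermansia alone, took 0.521 ± 0.462% against 6.12 ± 7.83% (-2.88, exact p 0.0142, adjusted p 0.0498), with a centred log-ratio difference of -3.15 (exact permutation, adjusted p 0.0742). Enterobacteria took 0.644 ± 0.119% against 0.544 ± 0.0490% (0.23, exact p 0.00550, adjusted p 0.0289), but their mean centred log-ratio was lower by 0.0787 in SHR. Genera known as reagent contaminants took 1.88 ± 0.247% against 1.48 ± 0.313% (0.36, exact p 0.00819, adjusted p 0.0344), but with a centred log-ratio difference of -0.0227 in the opposite direction. As mean centred log-ratios, which weigh every genus alike, 0 of the 20 lists with tested bacterial genera passed. That alternative changes the scale and the weighting together, so it does not tell which of them ended the calls.

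The remaining genus lists did not pass between the strains in females. Lactic acid bacteria took 7.31 ± 5.63% against 14.1 ± 9.26% (log2 odds -1.09, exact permutation, adjusted p 0.0831), Bacteroidales 29 ± 10.0% against 25.8 ± 13.3% (0.30, adjusted p 0.530), clostridia with toxin-forming members 5.73 ± 3.09% against 7.57 ± 3.04% (-0.49, adjusted p 0.194), and acetogens 2.17% against 1.61% (0.45, adjusted p 0.0675). Log2 odds were -0.18 in Bifidobacteriaceae (exact permutation, adjusted p 0.593), 0.33 in Campylobacterales (0.183), 0.32 in spirochaetes (0.0831) and 0.07 in cellulose degraders (0.732). They were 0.67 in Saccharibacteria (exact permutation, adjusted p 0.336), 0.65 in segmented filamentous bacteria (0.0675), -0.23 in Coriobacteriia (0.444) and -0.51 in Erysipelotrichia (0.183). Sutterellaceae stood at 0.39 (exact permutation, adjusted p 0.0969), mollicutes at 0.33 (0.355) and methanogens at 0.29 (0.137). As mean centred log-ratios the sign turned in Bacteroidales, spirochaetes, cellulose degraders and mollicutes. Without the 3 shallowest libraries, an alternative added later, lactic acid bacteria (-1.50, exact permutation, adjusted p 0.0128), the toxin-forming clostridia (-0.79, 0.0225), acetogens (0.53, 0.0258) and Erysipelotrichia (-0.79, 0.0258) passed. Over all genera limma called a single list member, a fall in Coriobacteriia. Adjusted over the list alone, 3 Coriobacteriia, 2 lactic acid bacteria, and 1 genus each of Bacteroidales, the toxin-forming clostridia, Erysipelotrichia and Akkermansia fell, and 1 genus each of Bacteroidales and Negativicutes rose.

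Flagellar genes were more frequent in SHR females. Flagellar motility averaged 797 ± 252 normalized reads against 413 ± 178 (log2 fold change 1.01 ± 0.29, limma adjusted p 0.0255, higher in 10 of 10) and Bacterial Chemotaxis 1426 against 802 (0.82 ± 0.22, limma adjusted p 0.0184, higher in 10 of 10). Capsule modification of the Campylobacter type (O-methyl phosphoramidate; 1.86 ± 0.45, limma adjusted p 0.00861), phosphoenolpyruvate phosphomutase (1.03 ± 0.22, adjusted p 0.00309) and toxin-antitoxin systems (0.83 ± 0.15, adjusted p 0.000827) also rose in 10 of 10. Energy-conserving hydrogenase (ferredoxin) fell by 2.07 ± 0.45 (limma adjusted p 0.00358), cyanophycin metabolism by 1.33 ± 0.28 (adjusted p 0.00309) and the At1g48360 cluster by 1.43 ± 0.33 (adjusted p 0.00709), each lower in 10 of 10. The SecY2-SecA2 export system fell by 1.84 ± 0.55 (adjusted p 0.0310) and Multidrug Resistance 2-protein systems by 1.27 ± 0.35 (adjusted p 0.0184), each in 9 of 10. In all 89 of 1057 functions were called, 39 higher and 50 lower, and 264 had an unadjusted p under 0.05.

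As lists of functions, motility and chemotaxis were higher in SHR females (mean log2 9.38 ± 0.297 against 8.79 ± 0.308, difference 0.59, exact permutation p 0.000747, adjusted p over lists 0.0134). Of its 5 members 3 rose over all functions and 4 adjusted over the list alone. Antibiotic resistance was lower (4.31 ± 0.0699 against 4.47 ± 0.111, difference -0.16, exact p 0.00198, adjusted p 0.0151; 2 of 26 members fell). So was peptidoglycan (7.15 ± 0.150 against 7.50 ± 0.247, difference -0.34, exact p 0.00251, adjusted p 0.0151; 1 of 10 members fell and 1 rose over all functions, 5 fell and 1 rose over the list alone). Differences that did not pass were 0.06 in butyrate and butanoate (exact permutation, adjusted p 0.882), -0.24 in propionate (0.271; 2 fell), 0.01 in lipopolysaccharide (0.986; 1 rose) and -0.20 in tryptophan (0.317; 1 fell). They were 0.02 in B vitamins and cofactors (exact permutation, adjusted p 0.914; 2 rose and 1 fell), -0.37 in menaquinone (0.0889), -0.10 in iron and heme (0.317; 1 rose) and 0.04 in sporulation (0.927; 1 rose). Sulfur stood at -0.11 (exact permutation, adjusted p 0.680), methanogenesis at 0.21 (0.317), polysaccharide breakdown near 0 (0.986) and bile acids and steroids at -0.07 (0.986). Nitrate and nitrite stood at -0.10 (exact permutation, adjusted p 0.680; 2 fell over the list alone), ribosome and tRNA at -0.01 (0.914; 1 rose and 1 fell) and oxidative stress at -0.25 (0.0846; 2 fell). With libraries scaled to equal totals every one of these function lists kept its sign, and motility and chemotaxis stood at 0.59, antibiotic resistance at -0.16 and peptidoglycan at -0.34 again (exact permutation, adjusted p 0.00994, 0.0305 and 0.0305).

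Of 125 archaeal species limma called 7 in females, 3 higher and 4 lower in SHR, on few reads and under names that were not checked against the reads. Reads named after the methanogen Methanosarcina flavescens rose by 1.81 ± 0.39 (limma adjusted p 0.00145, higher in 10 of 10). Reads of Natronomonas sp. YPL13, of a salt-loving genus, fell by 1.31 ± 0.27 (adjusted p 0.00114, lower in 10 of 10) and Methanothrix thermoacetophila by 1.29 (adjusted p 0.0442, lower in 9 of 10). Of 7 viruses 3 were called, of which 2 were Myoviridae phages (-4.29 ± 0.68, limma adjusted p 5.95e-08, lower in 10 of 10, and -2.96, adjusted p 9.98e-05, lower in 9 of 10). The other was Bacillus virus G (1.25 ± 0.34, limma adjusted p 0.00104, higher in 9 of 10). Of 89 eukaryotes only reads named after the yeast Saccharomyces eubayanus were called (-0.92 ± 0.24, limma adjusted p 0.0331, lower in 10 of 10).

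In males several species called in females were called again. Parabacteroides distasonis took 2.0 ± 2.56% of bacterial reads in SHR males (n = 7) against 0.213 ± 0.148% in WKY males (n = 7, log2 fold change 2.42 ± 0.54, limma adjusted p 0.0246). Bacteroides intestinalis took 0.324% against 0.0606% (2.09 ± 0.38, limma adjusted p 0.00273), and both were above the WKY median in 7 of 7. Clostridiales bacterium Choco116 (4.48 ± 0.74, limma adjusted p 0.00273) and Bifidobacterium catenulatum, a human gut bifidobacterium (0.86 ± 0.21, adjusted p 0.0442), rose in 7 of 7. Clostridium perfringens took 0.158% against 0.488% (-1.96 ± 0.37, limma adjusted p 0.00411, lower in 7 of 7). Limosilactobacillus reuteri took 1.03 ± 0.526% against 4.12 ± 2.29% (-2.40 ± 0.55, limma adjusted p 0.0327), also lower in 7 of 7 than the WKY median. Clostridium septicum (-2.21 ± 0.42, limma adjusted p 0.00411), Clostridium chauvoei (-2.16, adjusted p 0.00463), Clostridium isatidis (-1.86, adjusted p 0.00411) and Clostridium baratii (-1.83, adjusted p 0.0141) fell in 7 of 7.

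In all 25 of 4641 species were called in males, 11 higher and 14 lower in SHR (638 at an unadjusted p under 0.05). A fit of only the male groups, with fewer rats to estimate variance, called fewer species, as given below. In the main fit the variance was shared with females, and the Shannon index varied most in WKY males (SD 0.630). Where spread differs so, a shared variance can make the strain test in males too lenient. On percent of reads 173 were called, of which 164 were higher, so the split turned on the scale here too. Leaving out SHR male 1 left 13 and leaving out WKY male 7 gave 75. Counts were 14 without SHR male 3, 16 without SHR male 4, SHR male 5, SHR male 7 or WKY male 4, and 41 without SHR female 9, which enters through the shared variance. Of 1418 genera limma called 0 (164 at an unadjusted p under 0.05), where edgeR with TMM called 13 and DESeq2 26. Leaving out WKY male 7 gave 20 genera, and leaving out SHR female 9, SHR female 10, WKY female 1 or SHR male 6 gave 8, 7, 5 and 4. The simulated recovery of 2-fold species changes, with equal spread in all groups, was lower in males (38.8% against 53.7%). The shorter species list there was thus not read as smaller effects.

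**Figure D2:**
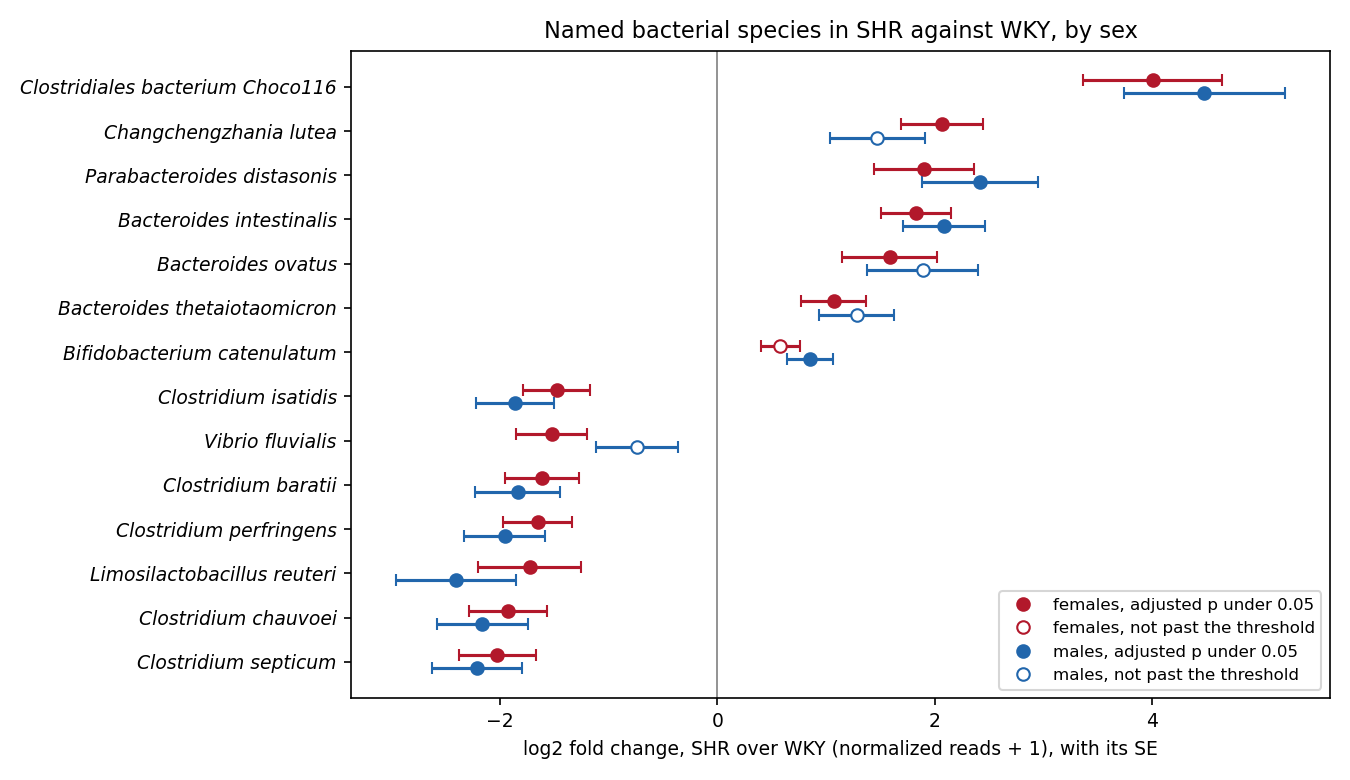
Log2 fold change (SHR minus WKY, with standard error) of named species in females and males, filled where the limma adjusted p was under 0.05. Clostridium septicum fell by 2.02 in females and 2.21 in males.

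The Shannon index was higher in SHR males (6.04 ± 0.190 against 5.36 ± 0.630, difference 0.681, exact permutation p 0.0163, adjusted p 0.0326), but on genera it did not pass (adjusted p 0.0513). Richness was higher by 265 (5155 ± 55.7 against 4891 ± 303 species, exact permutation p 0.0169, adjusted p 0.0338), but did not pass without thinning (5.43, adjusted p 0.874) or with a minimum of 10 reads (341, adjusted p 0.0944). Leaving out WKY male 6 lowered the Shannon difference to 0.514, and without any of 9 of the 14 males it no longer passed. Bray-Curtis composition did not pass (R2 0.160, exact permutation p 0.0775, adjusted p 0.155), while Aitchison (adjusted p 0.0186) and Jaccard distances (adjusted p 0.00699) did. Aitchison distances used unthinned reads, so depth can enter them, and SHR males had the shallower libraries. The log2 ratio of Firmicutes to Bacteroidetes averaged 0.84 ± 0.96 against 1.91 ± 1.38 (difference -1.07, exact permutation p 0.119). Among phyla 0 passed the exact permutation test in males and 4 had an unadjusted p under 0.05. On the percent scale Cyanobacteria came nearest (0.627% against 0.476%, adjusted p 0.0909), and on the size-factor scale they stood at -0.0086 and Firmicutes came nearest (-0.68, exact permutation p 0.0239, adjusted p 0.311). Bacteroidetes stood at 28.1 ± 13.1% against 18.8 ± 13.4% (adjusted p 0.180), Firmicutes at 47.3% against 56.5% (adjusted p 0.180), Verrucomicrobia at 1.89 ± 3.09% against 4.92 ± 6.57% (adjusted p 0.268) and Proteobacteria at 11.5% against 9.29% (adjusted p 0.159), which turned to -0.048 on the size-factor scale.

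No genus list passed in males by exact permutation (0 of 21, 4 at an unadjusted p under 0.05). Lactic acid bacteria took 9.53 ± 4.90% against 18.9 ± 9.75% (log2 odds -1.17, exact p 0.0326, adjusted p 0.220; 4 genera fell when adjusted over the list alone). Log2 odds were 0.46 in Campylobacterales, 0.45 in spirochaetes, 0.85 in segmented filamentous bacteria and 0.31 in methanogens (exact permutation, adjusted p 0.220 each) and 0.42 in butyrate producers (0.364). They were -0.74 in clostridia with toxin-forming members (exact permutation, adjusted p 0.260; 2 fell over the list alone), -1.92 in Akkermansia (0.364), 1.01 in Bacteroidales (0.315) and 0.41 in sulfate reducers (0.305). Enterobacteria stood at 0.29 (exact permutation, adjusted p 0.260), Negativicutes at 0.21 (0.547) and reagent contaminants at 0.36 (0.357). As mean centred log-ratios the sign turned in 9 lists, namely butyrate producers, enterobacteria, Campylobacterales, Negativicutes, reagent contaminants, Bifidobacteriaceae, acetogens, Erysipelotrichia and Sutterellaceae.

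Functions called in males numbered 26, 7 higher and 19 lower in SHR (203 at an unadjusted p under 0.05). A fit of only the male groups called fewer functions, as given below. Capsular polysaccharides (0.77 ± 0.20, limma adjusted p 0.0286), osmoregulated periplasmic glucans (0.61, adjusted p 0.0492), CMP-N-acetylneuraminate synthesis (0.54, adjusted p 0.0319), restriction-modification (0.38 ± 0.09, adjusted p 0.0267) and archaeal tRNA modification (0.30, adjusted p 0.0280) rose in 7 of 7. Multidrug Resistance 2-protein systems fell by 1.88 ± 0.40 (limma adjusted p 0.00938, lower in 6 of 7). Cyanophycin metabolism fell by 1.56 ± 0.33 (limma adjusted p 0.00938), glycerol fermentation to propanediol by 1.43 ± 0.31 (adjusted p 0.00938), CO-induced hydrogenase by 1.24 ± 0.30 (adjusted p 0.0182) and tungstate transport by 1.0 (adjusted p 0.0259), each in 7 of 7. Leaving out WKY male 7 gave 81 called functions and leaving out WKY male 6 gave 10. There were 12 without SHR male 1, 17 without SHR male 2, 46 without WKY male 1, 40 without WKY male 2 and 11 without WKY male 5.

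No function list passed in males by exact permutation (0 of 18, 5 at an unadjusted p under 0.05). Motility and chemotaxis differed by 0.62 (exact p 0.0420, adjusted p 0.151; 3 rose over the list alone) and nitrate and nitrite by -0.39 (exact p 0.00350, adjusted p 0.0524; 2 fell over the list alone). Ribosome and tRNA differed by 0.11 (exact permutation p 0.00583, adjusted p 0.0524) and peptidoglycan by -0.36 (exact p 0.00932, adjusted p 0.0559; 2 fell over the list alone). Oxidative stress differed by -0.18 (exact permutation, adjusted p 0.0682), iron and heme by -0.16 (adjusted p 0.171) and antibiotic resistance by -0.08 (adjusted p 0.763). With equal totals no list changed sign, and nitrate and nitrite passed (-0.39, exact permutation, adjusted p 0.0420). Of 125 archaea limma called 4 in males, with Candidatus Methanomassiliicoccus intestinalis, a gut methanogen, lower (-1.48 ± 0.33, limma adjusted p 0.00429, 7 of 7) and Methanosarcina lacustris (1.90 ± 0.45, adjusted p 0.00627, 7 of 7) and Halosimplex rubrum (1.62, adjusted p 0.0202, 7 of 7) higher in SHR. Of 7 viruses 4 were called, among them the same 2 Myoviridae phages (-2.56 ± 0.79, limma adjusted p 0.00566, lower in 7 of 7, and -2.08, adjusted p 0.0207, lower in 6 of 7) and a Podoviridae phage (6.02 ± 1.06, adjusted p 1.08e-06, higher in 7 of 7). Of 89 eukaryotes limma called reads named after the yeast Lachancea thermotolerans (1.11 ± 0.28, adjusted p 0.0219, higher in 7 of 7).

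Of the species called between the strains, 15 were called with the same direction in females and in males, 5 higher and 10 lower in SHR, where 0.307 would be expected of independent lists. Among the 25 species called in males 23 had the same sign in females, and 0 were called in both sexes with opposite signs. Of functions 11 were shared (2 higher, 9 lower; 1.157 expected), and 25 of 26 male calls had the same sign in females. No rat was part of both comparisons, but both came from 1 fit with a shared variance per feature, and related species can share reads. The lists are thus not independent, and the expected counts are no test of the overlap. Strain could not be told apart from processing order in either sex.

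The strain difference depended on sex in a single bacterial species, Pseudoalteromonas agarivorans, a marine bacterium by name, whose strain-by-sex value was -2.42 ± 0.45 (limma adjusted p 0.0133). Its normalized reads averaged 5.14 ± 2.25 in SHR females, 8.14 ± 3.16 in SHR males, 18.6 ± 7.19 in WKY females and 4.79 ± 2.67 in WKY males. It fell in SHR females (-1.69 ± 0.30, limma adjusted p 0.000959) and did not pass in males (0.73, adjusted p 0.325). At these levels a few reads make the difference, and 308 species had an unadjusted strain-by-sex p under 0.05. The Podoviridae phage also depended on sex (-4.28 ± 1.39, limma adjusted p 0.0197), with a strain difference of 1.74 in females (adjusted p 0.104) against 6.02 in males.

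Among genera limma called 0 for strain by sex (87 at an unadjusted p under 0.05; edgeR with TMM 0, DESeq2 2) and among functions 0 (82 at an unadjusted p under 0.05; edgeR with TMM 0, DESeq2 1). The lowest function p-values belonged to peripheral glucose catabolism (1.07), eukaryotic and archaeal large ribosomal subunits (-1.23) and inteins (1.01), at a limma adjusted p of 0.286. The strain differences of the Shannon index (interaction -0.0205, permutation p 0.942), richness (-60.3, p 0.633) and the Firmicutes to Bacteroidetes log2 ratio (0.80, p 0.332) did not differ between the sexes. Verrucomicrobia, called in females alone, had an interaction of -0.95 (permutation p 0.538), and butyrate producers 0.19 (permutation p 0.560).

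Between female and male SHR no bacterial species was called. Limma called 0 of 4641 species (167 at an unadjusted p under 0.05; edgeR with TMM 0, DESeq2 0) and 0 of 1418 genera (45 at an unadjusted p under 0.05; edgeR with TMM 0, DESeq2 0). It called 0 of 1057 functions (48 at an unadjusted p under 0.05; edgeR with TMM 0, DESeq2 2). The functions of lowest p were FOL commensurate regulon activation (1.21 ± 0.29, limma adjusted p 0.164), omega peptidases (-1.06 ± 0.26, adjusted p 0.164) and yersiniabactin, an iron carrier of enterobacteria (1.22, adjusted p 0.185). The Shannon difference was 0.00504 (exact permutation p 0.962), the richness difference -7.53 (exact p 0.802), the Firmicutes to Bacteroidetes difference -0.53 (exact p 0.233) and the Bray-Curtis R2 0.0740 (exact permutation, adjusted p 0.262). Actinobacteria came nearest among phyla (log2 odds -0.31, exact permutation p 0.0143, adjusted p 0.186). No genus list had an adjusted p under 0.451 (Bifidobacteriaceae -0.75, Coriobacteriia -0.43, Erysipelotrichia -0.76) and no function list one under 0.537. The Podoviridae phage was lower in females (-3.74, limma adjusted p 0.00161). The simulated recovery of 46.3% of 2-fold species changes, made with equal spread in all groups, leaves room for differences of that size.

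Bacteroides was called higher in female than in male WKY, but not under most of the alternative settings. The genus took 9.29 ± 5.32% of bacterial reads in females (n = 9) against 4.14 ± 3.33% in males (n = 7, log2 fold change 1.37 ± 0.39, limma adjusted p 0.0483, called in 18 of 48 settings). Bacteroides caecimuris, a mouse gut species, took 2.97 ± 1.61% against 1.21 ± 1.0% of bacterial reads (1.54 ± 0.36, limma adjusted p 0.0480, called in 22 of 49 settings). Lacticaseibacillus manihotivorans (-1.43 ± 0.28, limma adjusted p 0.0141) and Corynebacterium jeikeium, a skin bacterium (-1.41 ± 0.28, adjusted p 0.0154), were lower in females. Clostridioides, the genus of the diarrhoea pathogen C. difficile, took 0.429% against 0.896% (-0.93 ± 0.21, limma adjusted p 0.0311). Runella slithyformis (0.93, called in 20 of 48 settings) and Labilibaculum antarcticum (0.83, limma adjusted p 0.0480, 18 of 48) and the genera Paludibacter (0.97), Labilibaculum (0.83) and Salinimonas (0.80) were higher and Lacticaseibacillus (-0.77) lower in females. All of these but Paludibacter (8 of 9) lay beyond the male median in 9 of 9 females.

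In all 33 species (19 higher and 14 lower in females; 651 at an unadjusted p under 0.05), 34 genera (22 higher, 12 lower; 192) and 7 functions (all lower; 193) were called between the sexes of WKY. The functions of lowest p were ABC dipeptide transport at -0.92 ± 0.15 (limma adjusted p 0.00120) ABC oligopeptide transport at -0.76 ± 0.16 (adjusted p 0.0159) and D-allose utilization at -1.57 ± 0.31 (adjusted p 0.00883), each lower in 9 of 9 females than the male median. The split of species turned with the scale, as edgeR with library size alone called 25, of which 6 were higher and 19 lower in females. These counts hung on the shared fit and on single rats. The fit held 1 variance per feature for all 4 groups, while the Shannon index varied more in WKY. Its SD was 0.392 in WKY females and 0.630 in WKY males, against 0.218 and 0.190 in SHR. Where spread differs so, a shared variance can make a test within WKY too lenient and one within SHR too strict. Fitted on WKY rats alone, 4 species, 0 genera and 1 function were called. Leaving out any of 27 of the 33 libraries moved the species count more than 1.5-fold, to 1 without WKY male 4 and to 103 without WKY male 7, and many adjusted p-values stood at 0.0480. The genus count went to 0 without WKY male 2, male 4, male 5, female 4, female 6, female 7 or female 8, to 10 without male 6, to 22 without male 1 and to 60 without male 7. The function count went to 2 without WKY male 5, 3 without male 2, 4 without male 3 or male 4, 11 without female 6, 24 without male 1, 45 without female 1, 46 without female 9 and 74 without male 7, and to 17 without SHR female 1 and 19 without SHR male 4.

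Bacteroidales held 25.8 ± 13.3% in WKY females against 14.8 ± 11.7% in WKY males (log2 odds 1.27, exact permutation p 0.0640, adjusted p 0.989), with 5 genera higher over all genera and 11 adjusted over the list alone. Single genera fell over all genera in butyrate producers (Faecalibacterium, -0.65 ± 0.18, limma adjusted p 0.0474, called in 21 of 48 settings), Coriobacteriia (Olsenella, -0.48 ± 0.14, adjusted p 0.0483, 14 of 48) and Negativicutes (Acidaminococcus, -0.59 ± 0.15, adjusted p 0.0331, 36 of 48). Lactic acid bacteria and clostridia with toxin-forming members also held 1 fallen genus each. As lists 0 passed by exact permutation (0 at an unadjusted p under 0.05), no phylum passed (Bacteroidetes 1.21 and Firmicutes -0.74, adjusted p 0.522 each). The lowest adjusted p of a function list was 0.243. The log2 ratio of Firmicutes to Bacteroidetes was lower in females by 1.33 (exact permutation p 0.0517, adjusted p 0.207), the Shannon index differed by 0.0255 (exact p 0.921), richness by 52.8 (exact p 0.676), and the Bray-Curtis R2 was 0.0911 (exact permutation, adjusted p 0.262).

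At an adjusted p under 0.01 the authors' deposited tables of their own models hold 236 taxa for the strains in females (140 with a positive and 96 with a negative fold), 41 in males (22 and 19) and 463 for both sexes pooled (298 and 165). For functions the authors' deposited tables hold 85 in females, 16 in males and 148 pooled. In the tables of each sex the sign was opposite to SHR minus WKY throughout, as 0 of 158 species in females and 0 of 30 in males and 0 of 85 and 0 of 16 functions shared the sign of the fold changes here (Spearman rho -0.98, -0.99, -0.99 and -1.0). Turned around, 97 of the 158 and 20 of the 30 species and 65 of the 85 and 14 of the 16 functions were also called here. The authors' deposited tables of taxa carry an identifier and a name that mostly belong to different taxa. In females the deposited mean lay within 10% of the mean here in 187 of 187 taxa found by identifier and in 18 of 189 found by name, so identifiers were used. The authors' deposited table of their sequential taxa model holds a single species, Pseudoalteromonas agarivorans, with a log2 fold change of -2.70 (adjusted p 0.000397). Its reference levels are not given, so its sign was not compared with the strain-by-sex value here.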

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

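Single rats stood apart in some taxa, and chance alone would set a rat apart in about 1 in 20 groups. Of 425 sets of values 17 held such a rat, where 21.25 would be expected by chance, so these values are described and not explained. WKY female 5 had Actinobacteria at 9.31% of bacterial reads, where the other WKY females ran from 4.40% to 6.36%, and Chloroflexi, a phylum of filamentous bacteria mostly known from soil and water, at 0.222% against 0.103% to 0.135%. Vibrio fluvialis had 57.1 normalized reads in WKY female 1 against 358 to 685 in the other WKY females, and the genus Epilithonimonas had 53.8 in SHR male 1 against 31.7 to 39.0. The methanogen Methanosarcina barkeri had 27 normalized reads in WKY male 7 against 42.0 to 49.5, and the yeast Lachancea thermotolerans 31.2 in WKY female 7 against 7.37 to 15.1.

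SHR male 5 held 4 of these values. Reads named after Changchengzhania lutea, and so the genus Changchengzhania, stood at 944 normalized reads there against 173 to 255 in the other SHR males. Capsule modification of the Campylobacter type (O-methyl phosphoramidate) stood at 3.99 against 24.8 to 49.1, and the log2 size factor per read at -0.0544 against 0.153 to 0.302, which puts this rat beside the WKY rats on that measure. It stayed in every main test, and without it 16 species were called between the strains in males.

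Of the 2 Myoviridae phages called between the strains, the less reduced had 14.3 normalized reads in SHR female 9 against 0 to 2.6 in the other SHR females, and Bacillus virus G had 2.95 in SHR female 5 against 8.56 to 23.9. Among functions, osmoregulated periplasmic glucans had 475 in SHR female 9 against 274 to 356 and D-allose utilization 35.0 in SHR male 1 against 7.99 to 14.7. Yersiniabactin had 0.796 normalized reads in WKY male 5, peripheral glucose catabolism 0.773 in SHR male 7 and the eukaryotic and archaeal large ribosomal subunit 0.914 in SHR female 1, where the rest of each group had 0. Those last values stand for a single read.

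The strain effect turned on sex in 2 named taxa, and with 22.4% of simulated 2-fold species changes recovered by this test, few calls do not mean few such effects. Pseudoalteromonas agarivorans had a strain-by-sex value of -2.42 (limma adjusted p 0.0133) and a Podoviridae phage one of -4.28 (limma adjusted p 0.0197). The phage averaged 22 ± 45.2 normalized reads in SHR females, 393 ± 737 in SHR males, 1.08 ± 1.21 in WKY females and 0.308 ± 0.555 in WKY males, so its mean in SHR males came from few rats, and SHR male 4 had the highest viral share of all, 0.533% of reads.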

How the results depend on the processing

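Species counts between the strains depended on scale and depth. In females limma called 108, and 531 were called by edgeR with library size alone, 347 by limma on percent of reads, 244 by DESeq2 and 172 by edgeR with TMM. The filter at 100 gave 40 among the 337 species it kept, and thinned libraries gave 33. In males 25 became 159 with library size alone, 173 on percent of reads, 174 by DESeq2, 64 by edgeR with DESeq2's size factors, 59 with TMM, 10 with only the groups compared and 11 thinned. A depth term gave 409 in females and 93 in males, leaving out the 3 shallowest libraries 204 in females, and leaving out WKY male 5 and 6 gave 16 in males. The rises with library size alone and on percent of reads go with the shift of scale; for the rest the cause was not tested.

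Between the sexes of WKY, 33 species became 86 by edgeR with DESeq2's size factors, 175 by DESeq2, 79 with TMM, 53 with a pseudocount of 10, 70 with a depth term, 61 without the shallowest libraries, 13 without WKY male 5 and 6, 8 thinned, 4 without a filter, 4 with only WKY rats, 4 without WKY male 2 and 3, and 3 on percent of reads. Between the sexes of SHR a depth term gave 1 species and 1 genus. The strain-by-sex call of Pseudoalteromonas agarivorans was absent in thinned libraries (0 called). With group means of 4.79 to 18.6 normalized reads, the filter at 100 removed the species before the test, so the 0 there is no lost call.

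Genera between the strains in females went from 13 to 205 with library size alone, 23 with DESeq2's size factors, 52 by DESeq2, 23 with TMM, 154 on percent of reads, 179 with a depth term, 57 without the shallowest libraries, 25 without WKY male 5 and 6 and 21 without WKY male 2 and 3. In males 0 became 10 by edgeR with DESeq2's size factors, 50 with library size alone, 26 by DESeq2, 2 with the filter at 100, 13 with TMM, 75 on percent of reads, 6 with a depth term, 10 without the shallowest libraries, 12 without WKY male 5 and 6 and 2 without WKY male 2 and 3. Between the sexes of WKY 34 became 70 by DESeq2, 19 with the filter at 100 (376 genera kept) and 4 without WKY male 5 and 6. The count was 0 with library size alone, with only WKY rats, on percent of reads and without WKY male 2 and 3. For strain by sex DESeq2 called 2.

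Functions in females went from 89 to 231 with a depth term and 150 without the shallowest libraries. In males 26 became 53 with a mean of at least 10, 2 with only the groups compared, 53 with TMM, 81 by DESeq2, 94 with a depth term, 10 without WKY male 5 and 6 and 63 without WKY male 2 and 3. DESeq2 called 2 between the sexes of SHR and 1 for strain by sex, where a depth term gave 3. Between the sexes of WKY 7 became 23 with a mean of at least 10, 1 with only WKY rats, 40 with TMM, 66 by DESeq2, 22 with a depth term, 12 without the shallowest libraries and 31 without WKY male 5 and 6. The cause was not tested.

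In females archaea went from 7 to 11 without a filter and by DESeq2, viruses from 3 to 22 without a filter and eukaryotes from 1 to 5 on their own total and 2 by DESeq2. In males eukaryotes went from 1 to 2 on their own total. Genus lists in females went from 6 to 10 without the shallowest libraries (adding lactic acid bacteria, toxin-forming clostridia, acetogens and Erysipelotrichia) and to 0 as mean centred log-ratios (20 lists).

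The richness difference of females reversed to -76.7 without thinning (exact permutation, adjusted p 0.532), with the WKY libraries the deeper ones, and that of males shrank to 5.43 (adjusted p 0.874). With a minimum of 10 reads it was 341 in males (adjusted p 0.0944) and -55.2 between the sexes of WKY. On genera the Shannon difference was 0.523 in males (adjusted p 0.0513) and -0.0430 between the sexes of SHR, and PERMANOVA in females gave 0.178 (adjusted p 0.0876). Aitchison distances gave 0.133 in males (adjusted p 0.0186) and 0.106 between the sexes of WKY (adjusted p 0.0417), and Jaccard distances 0.0981 in males (adjusted p 0.00699). Scarce species weigh more in these distances than in Bray-Curtis distances, and Aitchison distances used unthinned reads, which lets depth enter. The cause was not tested.

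Leaving out each rat in turn gave 45 to 148 species in females, 13 to 75 in males, 0 between the sexes of SHR, 1 to 103 between the sexes of WKY and 1 for strain by sex. Genera ran from 9 to 27, 0 to 20, 0, 0 to 60 and 0 to 1, and functions from 61 to 129, 10 to 81, 0 to 1, 2 to 74 and 0 to 1. The Firmicutes to Bacteroidetes difference ran from -0.44 to -0.07 in females, -1.36 to -0.79 in males, -0.79 to -0.36 between the sexes of SHR and -1.62 to -1.05 between those of WKY. The Shannon difference ran from 0.566 to 0.736 in females, 0.514 to 0.832 in males, -0.0511 to 0.0436 between the sexes of SHR and -0.141 to 0.176 between those of WKY.

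The tests with TMM, on percent of reads, with a depth term, with pseudocounts for taxa, without named libraries other than each in turn, and with DESeq2 on functions were chosen only after the result was seen, as were those of lists with equal totals and of phyla on the size-factor scale. Named taxa and functions had 81 called results with 3175 alternative values, of which 484 were no longer called and 0 reversed, and 34 results were called under every setting. For bacteria and functions, 33 of the settings each left out 1 rat from the same limma fit. Some of those rats lay outside the comparison, so the settings are not independent methods. Clostridium septicum was called in 49 of 49 settings in females and in males. Limosilactobacillus reuteri was called in 21 of 49 in females and 39 of 49 in males, Bacteroides ovatus in 28 of 49, Bacteroides thetaiotaomicron in 35 of 49, and between the sexes of WKY Bacteroides caecimuris in 22 of 49 and the genus Bacteroides in 18 of 48.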

Other observations

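Eukaryotic reads carried names that are not gut residents. Plasmodium malariae, a malaria parasite of humans, was among the eukaryotes of highest mean in the authors' deposited normalized table. It averaged 132 ± 34.5 normalized reads in SHR females, 144 ± 45.4 in SHR males, 127 ± 35.6 in WKY females and 128 ± 35.1 in WKY males, and the strains did not differ in it (limma adjusted p 0.874 in females and 0.842 in males). The called eukaryotes were yeasts, Saccharomyces eubayanus in females (-0.92, limma adjusted p 0.0331) and Lachancea thermotolerans in males (1.11, limma adjusted p 0.0219). The 20 most abundant genera, mostly gut residents, held 48.4 ± 4.33% of all assigned reads in SHR females, 47.6 ± 4.83% in SHR males, 57.9 ± 5.22% in WKY females and 56.5 ± 11.4% in WKY males, so all other taxa together took a larger part in SHR.

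The share gap between the strains asked for a reason in the scale or in depth. The median species had a share higher by 0.364 log2 in SHR over the 33 rats, and with the top 20 genera removed from the total the gap was 0.0580, or 15.93% of it. That test was written before its result was seen, but its direction was set in advance. The 20 genera were picked by share in these data and held more of the reads in WKY, so removing them had to narrow the gap. The result does not tell whether dominant genera in WKY pressed down the other shares or those were larger in SHR for another reason. Depth could also play a part, but within strains the size factor per read was not tied to depth clearly (rho -0.333, permutation p 0.0626; SHR -0.115, WKY -0.565), which leaves that open. Pearson correlation gave -0.220 (permutation p 0.225).

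Rats with close numbers were more alike in composition, which might come from shared cages, litters or processing days. Over 256 pairs within strains the rank correlation of number gap and Bray-Curtis distance was 0.181 (1-sided permutation p 0.0103, as are all p-values of this paragraph), 0.324 among SHR (permutation p 0.00206) and 0.0194 among WKY (permutation p 0.384). Shared cages of rats of the same sex alone would leave no tie in pairs of opposite sex, where it was 0.145 (permutation p 0.0752) beside 0.209 in pairs of the same sex (permutation p 0.0202), so that test does not settle it. With the depth gap held constant the tie over both strains was 0.172 (permutation p 0.0147). That test was not run within SHR alone, where the tie lay, so it leaves depth open there. As Pearson correlation the tie was 0.153 (permutation p 0.0205), or 0.121 without the 2 rats of most distant number (permutation p 0.0533). These tests were chosen only after the result was seen, and the ranking within strains and the reading of the same-sex test were revised after an earlier version.

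The calls between the sexes of WKY could rest on few males. Against 33 species called with all rats, 4 were called without WKY male 2 and 3, and 13 without WKY male 5 and 6. Whether these were among the 33 was not counted, and these tests were chosen only after the result was seen. Over the 21 pairs of WKY males, the 15 pairs without WKY male 7 gave 0 to 21 calls and the 6 pairs with it 46 to 104. Losing any pair of males lowers the count unless the pair holds WKY male 7, so the tests do not single out either pair.

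Group names were moved among rats in 100 splits per comparison, the real one among them, and the count of splits with at least the real number of calls was read. For species it was 2 of 100 between the strains in females (real 108, highest other 372), 2 in males (25, 45), 100 between the sexes of SHR (0, 0), 1 between those of WKY (33, 1) and 4 for strain by sex (1, 2). For genera it was 2 in females (13, 215), 100 in males (0, 21), 100 in SHR (0, 0), 1 in WKY (34, 1) and 100 for strain by sex (0, 3). For functions it was 2 in females (89, 110), 3 in males (26, 52), 100 in SHR (0, 2), 3 in WKY (7, 12) and 100 for strain by sex (0, 75). Archaea gave 1 in females (7, 4) and 1 in males (4, 3), viruses 2 (3, 4) and 1 (4, 3), and eukaryotes 7 (1, 8) and 4 (1, 1). The split of females with 372 species had moved 14 of 19 rats and that of males with 45 had moved 12 of 14. As groups kept their sizes, the split of males exchanged nearly all rats between the strain names. It thus largely restates the strain contrast with its sign turned. The split of females leans the same way, so neither count stands for a grouping unrelated to strain. The 75 functions for strain by sex came with 12 of 33 rats moved. Splits with more calls than the real one that do not restate the strain contrast may point to structure of the samples. Its source was not tested.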
